A study of Mus musculus with 6 samples.

How the data were processed

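RNA was sequenced from pools of cells sorted as radial glia, the progenitors of the embryonic forebrain, from mouse embryos at embryonic day 12.5. Per the labels' protocols, forebrains were dissected and dissociated mechanically, and cells carrying the surface protein Prominin1 were taken by fluorescence-activated cell sorting. Stranded mRNA libraries were made with the KAPA kit and sequenced as paired-end reads on a HiSeq2500. The sequenced RNAs were those of the best integrity, chosen in pairs of 1 mutant and 1 control sample, per the labels' protocols. Per the labels' protocols the authors mapped the reads to GRCm38 with STAR 2.5.3a and quantified them with RSEM 1.3.0, with its setting for stranded libraries, on the GENCODE M15 annotation. The submitters' processing notes also name DESeq2 1.18. The deposited table holds the expected counts that the authors estimated per gene, as whole numbers with no scaling between libraries. How the estimates became whole and how isoforms were summed to genes is not given in the sources used here. RSEM shares reads that fit several places among them by estimation, so counts of pseudogenes and of near-identical gene copies are uncertain.

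The table has 52636 genes and 6 value columns, 1 per library, all of which were used. Each row pairs a gene ID with a symbol and a biotype. Gene positions were taken from GENCODE M21, which uses the same genome build, and 52403 of the genes were matched by ID. A symbol was shared by more than 1 gene ID in 97 cases. Among the list genes this concerned Lats2 and Aldoa, each with a second, lower-count ID. Columns were assigned to samples by the library names in the sample titles.

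The total expected count per library lay between 32997423 and 40744672, so 3 counts, the limit that a count of 0 allows, corresponded to at most 0.0909 CPM (counts scaled to a library total of 1e6). Such limits cover counting error only. Libraries of 1 genotype differed by far more than sampling noise, with chi-square per degree of freedom between 11.5 and 47.9, so none was a copy of another. The labels speak of separate pools, and do not say how many embryos or litters made up each one. The p-values measure the spread between these pools.

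The samples formed 2 groups of 3 pools, and the comparison was SmadNes against control. The counts, already whole, were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with genotype as the term. The filter left 16869 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Values are given as CPM with TMM scaling, as mean ± SD over the pools of a genotype, and log2 differences are SmadNes minus control with the standard error (SE) of the fit. Gene lists were compared with the other genes by camera (limma 3.58.1, voom log2 values, preset inter-gene correlation of 0.01, two-sided), adjusted over the 26 lists. Medians of a list are those of the edgeR log2 differences unless the voom scale is named. The lists covered BMP target genes and BMP ligands, receptors and antagonists, YAP targets, Hippo, Notch and Wnt genes, progenitor and neuronal states, forebrain regions, other cell types of the head, cell cycle, stress, metabolic and matrix genes, mitochondrial and ribosomal genes, and sex-linked genes.

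The replicate names SF3, SF4 and SF5_6 recur in both groups. Deviations from the group mean correlated across genes at 0.493, 0.697 and 0.724 between the libraries of 1 name, while libraries of different names correlated at or below -0.058. The first principal component (52.4% of the variance) and the second (23.9%) separated the names. The names therefore pair the samples, a decision made from these correlations and from the labels' mention of pairs. The common biological coefficient of variation was 0.198 without the replicate name as a block and 0.0556 with it. The fit without the block stayed the main one, as fixed before the data were examined, and blocked values stand beside results whose call they change.

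The genes named in the text followed a rule fixed before the data were examined. It took the targeted genes, the sort marker and a few pathway genes always. It took up to 12 genes per direction among called genes with a mean of at least 1 CPM and the same sign in all 3 pairs. Places left empty went to the genes with the smallest unadjusted p under the same conditions, which filled all 24 places here. It added up to 4 members per list with the smallest unadjusted p, and Xist with the Y-linked genes. Other genes named were chosen after their values were seen, and the text says so.

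The fits were tested on simulated counts for the SmadNes against control comparison, with 16671 genes and known changes. Without the block, 0% of 48 genes changed by 1.25-fold, 20% of 50 changed by 1.5-fold, 56.2% of 48 changed by 2-fold and 54.3% of 46 changed by 4-fold were called, with 0 false calls among 62. With the block these shares were 35.4%, 68%, 87.5% and 93.5%, with 20 false calls among 156. With a single list of the 26 shifted, camera called 0 of the unshifted lists without the block and 2 with it. Genes were drawn independently and in a single draw. The result therefore cannot show how often lists whose members move together are called falsely.

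Alternatives tried were 3 other scalings, 2 other low-count filters, DESeq2 1.42.0, limma-voom, the block with each tool, the removal of sex-linked, haemoglobin and mitochondrial genes, each library and each pair left out, and for lists an estimated correlation and fry. A fit without the block and without 1 library keeps that library's partner in the other group, so it mixes pool with genotype. The block with a pair left out, with another scaling, and with an estimated correlation or fry was added after seeing the data. The contrasts between pools, fitted with edgeR with genotype and pool as terms, and the tests by chromosome were also chosen after seeing the data. The mean count per gene limits what can be seen of rare transcripts, and splicing of the floxed genes could not be read from gene-level counts.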

Results

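Transcripts were measured in cells sorted from mouse embryos for the surface protein Prominin1 as cortical radial glia, the neural progenitors of the embryonic forebrain. The mutants, called SmadNes, carried 1 floxed and 1 wild-type copy of Smad1 and of Smad5 together with Nestin:Cre, which drives Cre recombinase in neural progenitors. The control littermates carried the same floxed copies and no Cre. Smad1 and Smad5 encode transcription factors that carry signals of bone morphogenetic proteins (BMPs). There were 3 pools of cells per genotype on a mixed CD1, 129/ola and C57BL6 background, named SF3, SF4 and SF5_6 in both groups. The control libraries held 34969342 (SF3), 40744672 (SF4) and 32997423 (SF5_6) expected counts, and the libraries labelled SmadNes held 38684963, 33731026 and 33732983. The comparison asks which transcripts differ in these sorted cells when Cre is present with these floxed alleles.

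Both targeted genes had higher counts in the libraries labelled SmadNes, in 3 of 3 pairs. Smad5 (ENSMUSG00000021540.16, GRCm38 chromosome 13, 56703010 to 56742377) stood at 292 ± 6.74 CPM in controls and 391 ± 18.8 CPM in SmadNes (SD, n = 3 each), 1.34-fold higher, with a log2 difference of 0.42 (SE 0.053). Smad1 (ENSMUSG00000031681.16, chromosome 8, 79338395 to 79399518) stood at 75.6 ± 2.58 and 88.5 ± 3.83 CPM, 1.17-fold higher, with a log2 difference of 0.23 (SE 0.052). Neither passed edgeR's quasi-likelihood test over all genes, with adjusted p of 0.965 for Smad5 and 1 for Smad1. With the replicate name as a block, Smad5 rose at an adjusted p of 0.00757 and Smad1 did not pass, at 0.257. DESeq2 without the block also called Smad5, at an adjusted p of 5.05e-06. A whole-gene count covers exons inside and outside a floxed part, so these values do not check the deletion, and every direction given here rests on the labels.

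**Figure D1:**
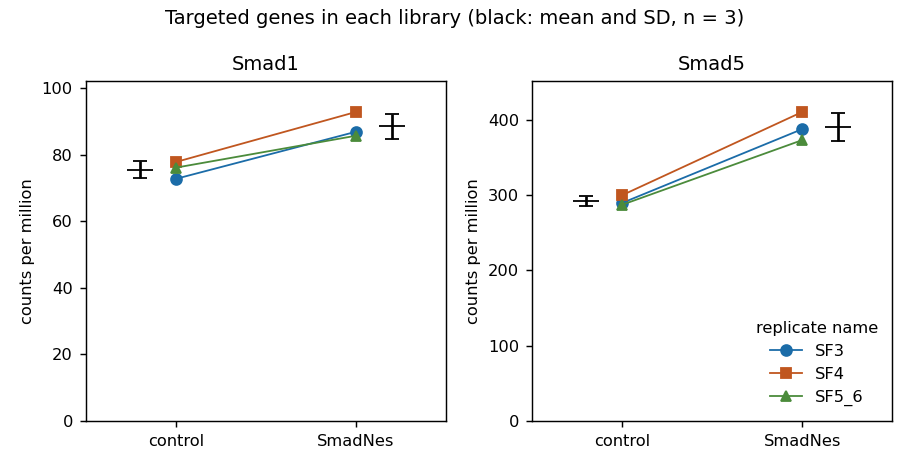
CPM of Smad1 and Smad5 (vertical axes, from 0) in the control and SmadNes libraries, with a line joining the libraries of 1 replicate name and black bars for mean and SD of 3 pools. Smad5 lay between 287.2 and 299.9 CPM in controls and between 373.3 and 410.7 CPM in SmadNes.

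Beyond the targeted genes, Ndn, Homer2, A230056P14Rik and Pop4 had some of the smallest p-values. Ndn, which encodes the imprinted growth suppressor necdin, stood at 112 ± 9.57 CPM in controls and 178 ± 12.3 CPM in the libraries labelled SmadNes (SD, n = 3 each), a log2 difference of 0.66 (SE 0.082). Homer2, a scaffold protein of synapses, stood at 116.0 ± 6.75 and 88.6 ± 5.49 CPM, a log2 difference of -0.39 (SE 0.068). The noncoding transcript A230056P14Rik stood at 3.48 ± 0.347 and 0.24 ± 0.171 CPM, 14.4-fold lower in SmadNes. Pop4, a subunit of ribonuclease P, stood at 53.4 ± 3.47 and 39.8 ± 1.66 CPM.

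None of these differences passed edgeR's test without the block, which called 0 of 16869 genes. At an unadjusted p below 0.05 it found 177 genes, 81 higher and 96 lower, and its smallest adjusted p was 0.965. Evenly spread p-values would give 843, but this fit counts the differences between pools as spread, so 843 is no measure of chance for it. The other regroupings of the libraries that part all 3 pairs gave 107, 80 and 125 such genes. With the replicate block 1051 genes, 469 higher and 582 lower, lay below that unadjusted p, against the same 843. With the block edgeR called 4 genes, of which Ndn (adjusted p 0.00757) and Smad5 rose and A230056P14Rik (0.012) and Homer2 (0.0453) fell, while Pop4 was at 0.0529. DESeq2 without the block called 7 genes, namely these 4 and Pop4, Rps19-ps6 and Gm35082, and limma-voom called 1, Gm35082. With the block DESeq2 called 14, among them Reln, Hmgn2 and, named after its values were seen, Nkx2-1, and limma-voom called 8. Gm35082, a noncoding gene named here after its values were seen, had 0 counts in each control library and 24, 21 and 16 counts in SmadNes.

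Ndn, Smad5, Smad1 and a further 9 genes filled the places for higher genes by smallest unadjusted p. Of the further 9, none passed edgeR's test on all libraries with or without the block. They included Hmgn2, a protein that binds nucleosomes, at 473 ± 11.4 and 559 ± 38.4 CPM, and Hddc3 at 14.7 ± 0.974 and 17.5 ± 0.173 CPM. The mitochondrial mRNA mt-Nd6 stood at 86.9 ± 2.00 and 97.2 ± 3.79 CPM. Pseudogenes and noncoding genes made up the rest. Rps19-ps6 stood at 4.45 ± 0.627 and 8.63 ± 0.752 CPM, Mrpl48-ps at 1.06 ± 0.329 and 2.10 ± 0.237 CPM, AC174776.1 at 0.137 ± 0.237 and 3.10 ± 1.72 CPM, Gm15506 at 3.999 ± 0.219 and 5.51 ± 0.579 CPM, and Gm37298 at 2.28 ± 0.217 and 3.64 ± 0.779 CPM. CT010467.1, which lies in a ribosomal RNA repeat, stood at 46.1 ± 5.48 and 78.5 ± 23.0 CPM. Counts of pseudogenes can hold reads of their parent genes.

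On the lower side, Myo7a, the myosin of inner-ear hair cells, stood at 23.9 ± 2.17 CPM in controls and 4.49 ± 3.65 CPM in SmadNes, with a log2 difference of -2.40 (SE 0.629). With the block its adjusted p was 0.0944, and it fell when the pair SF3, SF4 or SF5_6 was left out of that fit (adjusted p 0.0427, 0.000225 and 1.18e-06). Ryr3, a calcium release channel, stood at 21.1 ± 1.66 and 14.97 ± 1.64 CPM, Thsd4 at 20.8 ± 0.935 and 15.8 ± 0.706 CPM, and Plekha6 at 64.1 ± 1.84 and 55.2 ± 1.09 CPM. The semaphorin Sema6c stood at 97.8 ± 4.59 and 85.6 ± 1.30 CPM, and the transcription factor Arnt2 at 257 ± 10.7 and 228 ± 5.82 CPM. Saxo2 (2.39 ± 0.401 and 1.32 ± 0.172 CPM), E130006D01Rik (2.06 ± 0.139 and 1.26 ± 0.114 CPM) and Nat8f1 (2.18 ± 0.199 and 1.44 ± 0.101 CPM) completed the set. With all libraries, none of these 9 passed edgeR's test with or without the block, and 9 of the 24 genes of both directions lie on chromosome 7.

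**Figure D2:**
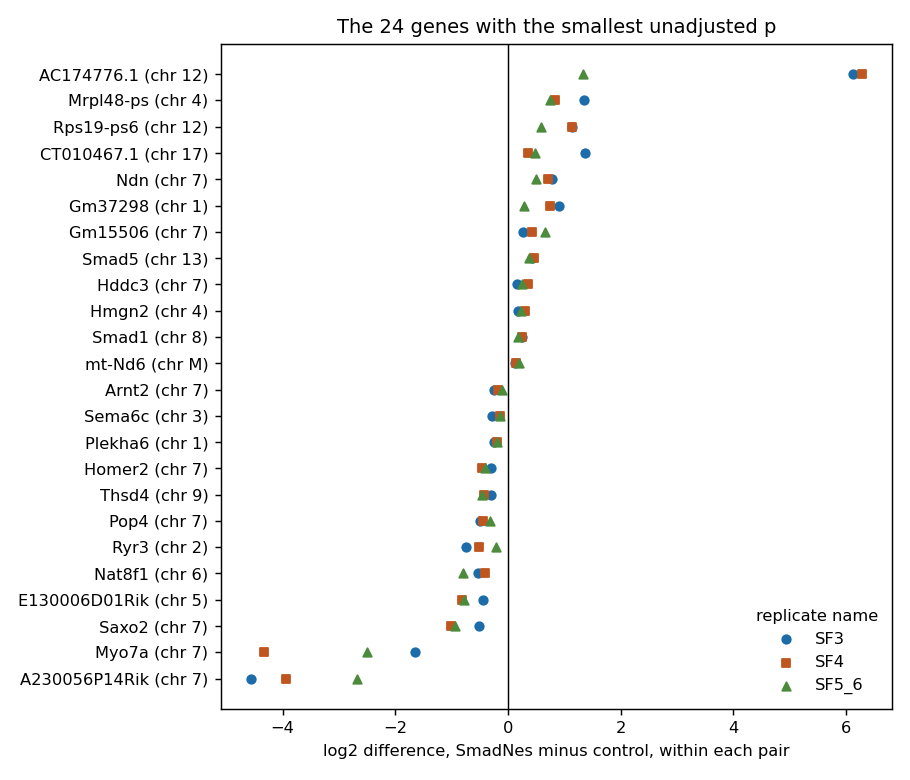
Log2 difference, SmadNes minus control, within each pair of pools (horizontal axis) for the 24 genes with the smallest unadjusted p, labelled with their chromosome. Each symbol is 1 pair, and for each gene all 3 pairs lie on 1 side of 0, as the rule for naming them required.

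BMP pathway transcripts did not differ detectably between the genotypes with all 6 libraries. Among BMP target genes, edgeR called 0 of 17 tested members over all genes and 0 when adjusted over the list alone. Id1, a BMP-induced inhibitor of differentiation, stood at 9.52 ± 5.98 CPM in controls and 7.73 ± 3.00 CPM in the libraries labelled SmadNes (SD, n = 3). Id3 stood at 26.8 ± 22.1 and 21.3 ± 11.7 CPM. Within the pairs SF3, SF4 and SF5_6 the log2 differences were -0.122, 0.097 and -0.565 for Id1. For Id3 they were 0.052, 0.045 and -0.586, so the lower values lay mainly in the SF5_6 pair. Id4 stood at 374 ± 53.2 and 409 ± 50.4 CPM, higher in 3 of 3 pairs. The list median was -0.02 and its mean -0.07 on the log2 scale, while camera pointed up (adjusted p 0.721), so their signs differ. Of the BMP ligands, receptors and antagonists, 0 of 19 were called (median log2 difference -0.01, camera adjusted p 0.788), with Bmpr1a at 161 ± 10.9 and 168 ± 14.2 CPM and Grem1 at 0.788 ± 0.208 and 0.537 ± 0.0475 CPM. Without the control library SF5_6, in which Id1 and Id3 were highest, camera placed the BMP targets higher at an adjusted p of 0.00588. That fit kept SmadNes SF5_6 without its partner and so mixed pool with genotype. With the block and the SF5_6 pair left out, camera also placed the BMP targets higher (voom median 0.080, adjusted p 0.0173). With the block they did not pass on all pairs (0.662), nor without the SF3 or SF4 pair (medians -0.048 and -0.054, adjusted p 0.181 and 0.0748). The median of the BMP targets was higher in the SF5_6 pools than in SF3 (log2 0.277) and SF4 (0.257).

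YAP targets and Hippo genes also showed no called member. Yap1, the effector of the Hippo pathway, stood at 118 ± 26.0 CPM in controls and 124 ± 20.3 CPM in SmadNes. Its targets Cyr61 (Ccn1) and Ctgf (Ccn2) stood at 9.94 ± 1.46 and 10.3 ± 1.21 CPM, and at 3.77 ± 2.11 and 3.50 ± 0.832 CPM. Of 21 YAP targets 0 were called (median 0.02, camera adjusted p 0.571), and of 23 Hippo components 0 were called (median 0.03, adjusted p 0.325), with Lats1 at 159 ± 3.88 and 167 ± 3.22 CPM. Camera placed the YAP targets higher at an adjusted p of 0.0055 without the control library SF5_6. With the block it did so without the SF5_6 pair (0.0466), and not without the SF3 (0.65) or SF4 pair (0.145). Among 16 Notch genes, 0 were called, with Hes1 at 28.7 ± 4.88 and 31.8 ± 3.40 CPM and Hey2 at 11.3 ± 2.19 and 13.97 ± 3.10 CPM. The Notch list did not pass camera (adjusted p 0.121), but did with the block (higher, adjusted p 0.00174, and 0.728 with an estimated correlation), and without SmadNes SF3, control SF4 or control SF5_6 (higher, 0.0322, 0.0408 and 0.00199), with pair medians of 0.211 in SF3, 0.080 in SF4 and -0.020 in SF5_6. Of 15 Wnt targets 0 were called over all genes (median 0.08, camera adjusted p 0.162), and with the block Tnfrsf19, at 174 ± 21.9 and 200 ± 20.1 CPM, was called when adjusted over the list alone. The Wnt list was placed higher without SmadNes SF3 (adjusted p 0.0152) or control SF5_6 (0.000167). With the block camera placed it higher without the SF5_6 pair (1.38e-07), and not without the SF3 (0.627) or SF4 pair (0.56).

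Genes of the ventral telencephalon, the source of cortical interneurons, were lower in the libraries labelled SmadNes. The median log2 difference of 20 tested members was -0.59, 19 of the 20 were negative, and 14 were lower in all 3 pairs. Chance would give 2.5 if genes were independent, but these members moved together, with an estimated correlation of 0.75. Gad1, which makes the transmitter GABA, stood at 9.94 ± 5.73 CPM in controls and 6.60 ± 5.91 CPM in SmadNes (SD, n = 3), Sp9 at 9.92 ± 6.24 and 5.83 ± 6.22 CPM, Slc32a1 at 4.99 ± 3.05 and 2.86 ± 2.48 CPM, and Lhx6 at 7.17 ± 4.33 and 4.23 ± 0.444 CPM. EdgeR called no member over all genes, with or without the block, and none over the list alone without it. DESeq2 and limma-voom with the block called Nkx2-1 over all genes (adjusted p 7.5e-05 and 0.027). With the block, 10 members fell when adjusted over the list alone (Dlx1, Dlx2, Dlx5, Nkx2-1, Gad1, Gad2, Sp9, Six3, Isl1 and Slc32a1), of which Dlx1, Dlx2, Dlx5, Nkx2-1, Gad2, Six3 and Isl1 are named here after their values were seen. Camera placed the list lower at an adjusted p of 0.0056, and at 1.44e-13 with the block. The call was lost with an estimated correlation (adjusted p = 0.939, and 0.598 with the block), and without SmadNes SF3, SmadNes SF4 or control SF5_6, at adjusted p of 0.366, 0.426 and 0.73.

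Radial glia genes differed little. None of 24 was called, the median log2 difference was 0.04, and the list did not pass camera (adjusted p 0.177), though it did with the block (higher, adjusted p 0.00108, and 0.728 with an estimated correlation), and without SmadNes SF3, control SF4 or control SF5_6 (higher, 0.0152, 0.0393 and 0.00632), with pair medians of 0.102 in SF3, 0.042 in SF4 and -0.009 in SF5_6. The sort marker Prom1 stood at 120 ± 11.8 and 124 ± 11.97 CPM, Nes, which encodes nestin, at 442 ± 51.8 and 479 ± 76.8 CPM, and Emx2, a patterning gene of the dorsal cortex, at 126 ± 29.3 and 145 ± 22.3 CPM. Emx2 was called with the block when adjusted over the list alone. The sorted cells also held many neuronal transcripts, with Tubb3 of the cortical neuron list at 904 ± 54.8 and 848 ± 30.6 CPM. The mean log2 CPM of that list was 7.603 in control SF3 and 7.076 in control SF5_6, against 6.748 and 7.15 for radial glia genes. Differences between these libraries therefore need not lie in radial glia. Of 19 genes of intermediate progenitors 0 were called (median -0.002, camera adjusted p 0.874), with Insm1 at 193 ± 46.2 and 172 ± 54.7 CPM. That list was placed lower without SmadNes SF4 (adjusted p 0.0185) or control SF5_6 (0.0238), and higher without SmadNes SF5_6 (2.49e-05). Of 26 genes of cortical neurons edgeR called 0 (median -0.09). It passed camera with the block (lower, adjusted p 0.00786, and 0.728 with an estimated correlation) and without control SF5_6 (lower, 0.0188), against 0.571 for all libraries without the block, and its pair medians were -0.130 in SF3, 0.005 in SF4 and -0.001 in SF5_6. Its members moved apart, with Reln of Cajal-Retzius cells at 749 ± 163 and 949 ± 256 CPM, and Mapt, the microtubule protein tau, at 130 ± 36.4 and 108.0 ± 16.1 CPM, and both were called over the list alone with the block. Over all genes, DESeq2 and limma-voom with the block called Reln (adjusted p 3.03e-10 and 0.0271).

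Among markers of other regions and cell types, edgeR called no member over all genes. The cortical hem and choroid plexus list (21 tested, median -0.06, camera adjusted p 0.721) included Ttr at 175 ± 32.2 and 146 ± 45.8 CPM, and was placed lower without control SF3 (0.000664) and higher without control SF5_6 (0.000149). In the diencephalon, midbrain and eye list (13 tested, median -0.10, adjusted p 0.64), Shh stood at 1.56 ± 2.22 and 0.470 ± 0.768 CPM and was called over the list alone with the block. That list was placed lower without control SF4 (0.0335) or SmadNes SF5_6 (0.0103). Erythroid genes (14 tested, median -0.51) did not pass camera (adjusted p 0.721), but did with the block (lower, adjusted p 3e-05, and 0.728 with an estimated correlation), and Hbb-bt stood at 27.6 ± 13.7 and 16.9 ± 8.07 CPM. With the block, Hbb-bt and Slc4a1, the latter named after its values were seen, fell when adjusted over the list alone, and DESeq2 with the block called Hbb-bt over all genes (adjusted p 0.00704). Hbb-bt lies on chromosome 7. Its log2 differences in SF3, SF4 and SF5_6 were -0.501, -0.356 and -1.121, against -0.157, 0.121 and -0.895 for Hba-a1. Without control SF4 the erythroid genes were placed lower (0.00375) and without control SF5_6 higher (0.0497). Endothelial genes (14 tested, median 0.03, adjusted p 0.788) and microglial genes (18 tested, median 0.03, adjusted p 0.64) did not pass with or without the block, with Kdr at 14.1 ± 1.86 and 15.8 ± 1.4 CPM and Cd68 at 4.89 ± 0.795 and 5.49 ± 1.52 CPM. Endothelial genes were placed higher without SmadNes SF4 (0.00438). Microglial genes were placed lower without control SF4 (0.000216) and higher without control SF3 (0.00396) or SmadNes SF4 (5.89e-08). Mesenchymal genes (23 tested, median 0.16, adjusted p 0.413) passed with the block (higher, adjusted p 0.00205, and 0.753 with an estimated correlation), without SmadNes SF4 (5.73e-14) and without control SF5_6 (0.0055). Their pair medians were 0.434 in SF3, -0.442 in SF4 and 0.267 in SF5_6, and 0 of 23 were higher in all 3 pairs.

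Transcripts of cytosolic ribosomal proteins were slightly higher in the libraries labelled SmadNes. Of 75 members, 70 had a positive log2 difference and 36 were higher in all 3 pairs. Chance would give 9.4 if genes were independent, but the estimated correlation of the members was 0.201. The median was 0.05 on the log2 scale, 1.03-fold. Rpl12 stood at 317 ± 12.2 and 345 ± 1.55 CPM, and Rpl39 at 140.2 ± 4.61 and 154 ± 5.71 CPM. None was called on its own. Camera placed the list higher at an adjusted p of 8.29e-16, a call lost with an estimated correlation (adjusted p = 0.939, and 0.258 with the block). The 13 mitochondrially encoded mRNAs were also placed higher (median 0.06, adjusted p 0.0113, and 0.939 with an estimated correlation), with mt-Atp6 at 122 ± 18.2 and 149 ± 37.9 CPM. The list's call was lost without SmadNes SF3 (adjusted p 0.369) or control SF5_6 (0.343). With the block, mt-Nd6 rose when adjusted over the list alone. Counts from the ribosomal RNA locus (CT010467.1 and Gm42418, the latter named after its values were seen) made up 0.523%, 0.583% and 0.556% of the control libraries SF3, SF4 and SF5_6 and 1.124%, 0.966% and 0.625% of the SmadNes libraries, higher in 3 of 3 pairs.

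Cell cycle genes were also placed higher by camera, with small differences. The 30 S phase genes had a median log2 difference of 0.07 (adjusted p 0.00404) and the 34 genes of G2 and M phase one of 0.06 (adjusted p 0.0113), and both calls were lost with an estimated correlation (adjusted p = 0.939 for each). Pcna, the clamp of DNA polymerase, stood at 176 ± 15.6 and 191.0 ± 13.8 CPM, and Cenpf at 259 ± 41.0 and 281 ± 32.1 CPM. None of the 64 members was called. Without the control library SF3 the medians on the voom scale turned negative, at -0.015 for S phase (adjusted p 0.452) and -0.061 for G2 and M phase (0.000282). Without SmadNes SF5_6 they were -0.008 (0.63) and -0.018 (0.533). Both fits kept a library without its partner and so mixed pool with genotype. With the block and the SF3 pair left out the medians were 0.030 and 0.016, and neither list passed camera (0.122 and 0.471). Both passed with the SF5_6 pair left out (0.051 and 0.066, adjusted p 0.00309 and 2.48e-05). With the block, all pairs and an estimated correlation neither passed (0.728 for each). In the pairs SF3, SF4 and SF5_6 the S phase median was 0.148, -0.041 and 0.095, and that of G2 and M phase 0.171, -0.051 and 0.061.

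The remaining lists had no called member and did not pass camera. They were immediate-early genes (24 tested, median -0.02, adjusted p 0.506), p53 targets (19 tested, median 0.03, adjusted p 0.162), sterol synthesis (24 tested, median 0.01, adjusted p 0.492), hypoxia and glycolysis (30 tested, median 0.02 with a mean of -0.004, adjusted p 0.359) and extracellular matrix (29 tested, median 0.10, adjusted p 0.177). The matrix list passed with the block (higher, adjusted p 1e-04, and 0.728 with an estimated correlation), and without SmadNes SF4 (2.88e-06) or control SF5_6 (0.00026), with pair medians of 0.225 in SF3, -0.058 in SF4 and 0.025 in SF5_6. Without control SF5_6 the p53 targets (0.00632) and the hypoxia list (0.0497) were also placed higher. With the block camera placed the p53 targets higher without the SF5_6 pair (0.0122), and not without the SF3 (0.468) or SF4 pair (0.297). The p53 target Eda2r stood at 7.58 ± 0.504 and 9.69 ± 0.959 CPM, and the glycolytic enzyme Pfkp at 30.0 ± 3.83 and 25.6 ± 3.48 CPM.

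**Figure D3:**
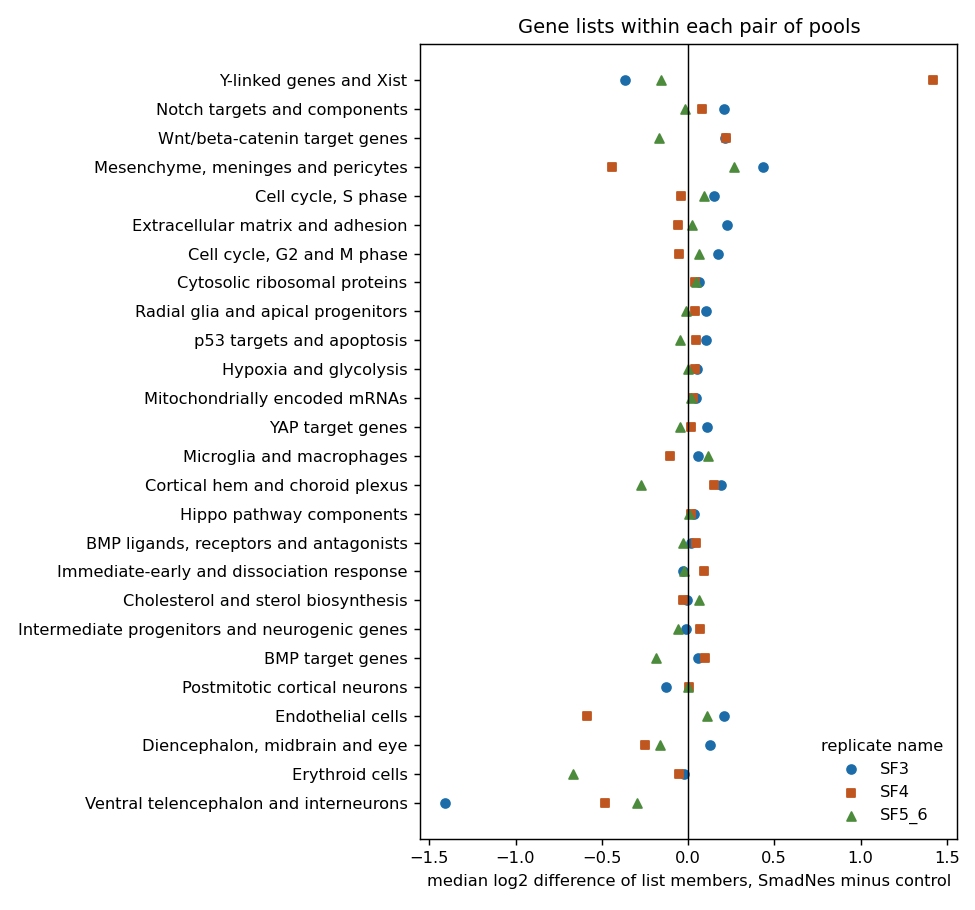
Median log2 difference, SmadNes minus control, of the tested members of each gene list (horizontal axis), with 1 symbol per pair of pools. The ventral telencephalon list had medians of -1.411 in SF3, -0.480 in SF4 and -0.297 in SF5_6, and the ribosomal protein list lay between 0.041 and 0.062.

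The pools held cells of both sexes in differing shares. Xist, expressed from the inactive X chromosome, stood at 1538, 2974 and 2214 CPM in the control libraries SF3, SF4 and SF5_6 and at 2158, 1790 and 2495 CPM in SmadNes. The Y-linked Ddx3y stood at 32.2, 14.1 and 26.2 CPM in controls and 24.9, 40.1 and 23.5 CPM in SmadNes. Kdm5d, Uty and Eif2s3y were likewise lowest in control SF4, at 19.2, 9.90 and 15.3 CPM. No sex-linked gene was called, and the list of 5 did not pass camera (adjusted p 0.164, and 0.0175, higher, without control SF3). Xist and Ddx3y moved in opposite directions within each pair. A test of their joint direction therefore cannot tell whether the sex mix differed between the genotypes.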

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

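The replicate block with a pair of pools left out, with another scaling, or with an estimated correlation or fry was chosen after seeing the data. The count of changed genes was 0 under 3 other scalings, 2 other filters, the removal of sex-linked, haemoglobin and mitochondrial genes, and each single library left out (0 to 0). It was 7 with DESeq2 and 1 with limma-voom. With the replicate block it was 4, and 14 with DESeq2 and 8 with limma-voom. With the block and both libraries of SF3, SF4 or SF5_6 left out it was 10, 48 and 149, and with the block and DESeq2 size factors, upper-quartile scaling or library size alone it was 4, 3 and 4. The fits with a pair left out have fewer residual degrees of freedom than the 2 of the block on all pairs. On simulated counts the latter gave 20 false calls among 156, and the former were not simulated. Of 10 splits of the 6 libraries into 3 and 3, 10 gave as many calls without the block as the real one, which gave 0, and the highest other split also gave 0. The 10 splits, and the 4 that part all pairs, are too few for a share under 0.05. With the block 1 of these 4 reached the real 4, and the highest other gave 1.

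Smad5 kept its direction in every alternative. Its log2 difference passed the test with DESeq2 (0.414), with the block (0.418), with the block and DESeq2 (0.413) or limma-voom (0.418), and with the block and SF3 (0.418), SF4 (0.398) or SF5_6 (0.438) left out. It also passed with the block and DESeq2 size factors (0.414), upper-quartile scaling (0.423) or library size alone (0.407), and ranged from 0.380 to 0.450 with 1 library left out. Smad1 ranged from 0.191 to 0.250 with 1 library left out and passed only with the block and SF5_6 left out, at 0.256. Of 3357 comparisons of 130 named genes with an alternative, 3283 stayed on their side of the test and 74 became calls (68 of them with the block). The sign changed in 75 comparisons, all uncalled on both sides, among them Id1 (-0.652 to 0.342) and Id3 (-0.879 to 0.590).

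Of 26 lists, camera called 5, and 0 with an estimated correlation, 0 with fry, and 11 with the block. With the block it called 0 with an estimated correlation, 0 with fry, and 6 (2 higher, 4 lower), 14 and 16 with SF3, SF4 or SF5_6 left out. With 1 library left out it called from 5 (SmadNes SF5_6) to 16 (control SF5_6). Of 10 splits 9 gave as many calls as the real 5, and the highest other gave 18, which points to a structure of the samples by pool. With the block 3 of 4 gave as many as the real 11, and the highest other gave 15. With 1 library left out, voom medians ranged from -1.644 to -0.011 for ventral telencephalon, -0.015 to 0.127 for S phase (-0.008 without SmadNes SF5_6), and -0.061 to 0.134 for G2 and M phase (-0.018 without SmadNes SF5_6). They ranged from -0.092 to 0.138 for intermediate progenitors, -0.287 to 0.322 for the hem, -1.011 to 0.389 for erythroid, -0.213 to 0.267 for endothelial and -0.833 to 0.933 for microglial genes. Erythroid genes stood at 0.379 without control SF5_6. With the block, the Y-linked list was at -0.298 without the SF4 pair and the hem list at 0.140 without the SF5_6 pair. With edgeR and camera on all 6 libraries, the block changed no other call than those given here and in the report. With a pair left out the block also called Myo7a (each pair), Dcn and CT010467.1 (SF4), and AC174776.1, CT010467.1, Gm37298, Rps19-ps6, Hmgn2, Ryr3, Arnt2 and Wnt5a (SF5_6), among others. Lists also placed higher without SF5_6 were BMP targets (adjusted p 0.0173), BMP ligands (0.0275), YAP (0.0466), Wnt (1.38e-07) and p53 targets (0.0122), the hem (5.03e-09) and the Y-linked list (0.0141). Without SF4, sterol synthesis was placed higher (0.0488), and the hem (0.00353) and Y-linked (0.00434) lists lower. Without SF3, the hem (6.5e-05) and diencephalon (0.0071) lists were placed lower. Where 1 library was left out without the block, its partner of the same name stayed in the other group. Pool and genotype were mixed in those fits. The cause of these differences was otherwise not tested. A group left with 2 libraries shares the spread of the other group in these fits.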

Other observations

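The contrasts between pools, and the tests of a chromosome 7 stretch, of Smad5 and of ventral genes, were chosen after the results were seen, as were the genes named for the pools other than Id1 and Id3. The pools of both genotypes differed far more by their name than by genotype, and in region and cell type (2 libraries per pool, genotype kept as a term). Between any pools, 4864 of 16869 genes were called, with 4230 between SF5_6 and SF4, 4618 between SF5_6 and SF3, and 605 between SF4 and SF3. Against SF4, SF5_6 held more ventral telencephalon transcripts, of which 17 of 20 rose (median log2 difference 2.56, camera adjusted p 8.86e-14, and adjusted p = 0.466 with an estimated correlation). Nkx2-1 of the medial ganglionic eminence rose by 5.96 (SE 0.249) and Dlx2, a factor of interneuron precursors, by 3.06 (SE 0.243). In the same contrast 17 of 19 intermediate progenitor genes fell (median -0.49, adjusted p 4.25e-11, and 0.466 with an estimated correlation), with Eomes at -0.75 (SE 0.043). Of 26 cortical neuron genes 15 fell, Neurod6 by 1.32, and 5 rose (median -0.286, camera adjusted p 0.000193, and 0.566 with an estimated correlation). Of the microglial genes 17 of 18 rose, with the receptor Csf1r at 2.36, and between SF4 and SF3 17 of 18 fell, with Csf1r at -2.85.

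BMP targets differed between pools as well. From SF3 to SF5_6, 11 of 17 rose and 1 fell (median 0.28, adjusted p 7.09e-05, and 0.379 with an estimated correlation). Genes of the cortical hem and choroid plexus moved with them, with 17 of 21 rising in that contrast (median 0.92, adjusted p 3.92e-10, and 0.375 with an estimated correlation) and 13 of 21 against SF4, and Msx1 and Msx2 belong to both lists. Against SF4, 6 of 17 BMP targets rose in SF5_6 and 3 fell (median 0.257, camera adjusted p 0.0442, and 0.627 with an estimated correlation). Among those higher were Id1 (1.05), Id3 (1.54, SE 0.145) and Msx1 (1.06). Of 19 BMP ligands, receptors and antagonists 6 rose, among them Bmp4 (1.59), and 3 fell. Id1 and Id3, which were named by rule, differed less between genotypes (-0.299 and -0.33).

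Chromosome 7 carried more genes with low p than its share, 57 of 1328 with a blocked p below 0.01 against 21.7 expected (ratio 2.63, Fisher p 1.04e-11, 43 of them lower in the libraries labelled SmadNes), and the ratio was 2.52 without the SF3 pair, 1.49 (Fisher p 0.00448) without the SF4 pair and 1.5 (Fisher p 0.00317) without the SF5_6 pair. The 4 splits that part all pairs are too few for a share under 0.05: 1 reached the real 2.63, and the highest other gave 1.04. Low counts and pseudogenes are argued against by a ratio of 2.57 among protein-coding genes of at least 10 CPM. Among as many top genes between SF5_6 and SF4 the ratio was 0.79. That value covers only the cell mix that differs between those pools, so another difference in mix between the genotypes stays open. The genes were spread unevenly along the chromosome (permutation p 0.0077). Shares were highest from 60 to 70 Mb (5 of 43, 11.6%) and from 80 to 90 Mb (9 of 83, 10.8%). The Fisher and permutation p-values treat genes as independent, which genes measured in the same 6 libraries need not be. The excess may reflect a stretch of another strain's chromosome 7 commoner in one genotype of this mixed background, a hypothesis whose test was written after the genes were seen and which the table, holding no variants, cannot settle.

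Smad5 was higher in the libraries labelled SmadNes, whereas a deletion that lowered its transcript would lower the count. A whole-gene count does not check the deletion. Reads moved between Smad1 and Smad5 are argued against, since both were higher in all 3 pairs. The summed CPM of Smad1, Smad5 and Smad9 was also higher (log2 0.377, SD 0.044 over pairs). That sum was formed after both rises were seen and largely restates them. A larger share of radial glia is argued against by Emx2, which had the highest difference in that list, 0.225 (SE 0.048), below the 0.418 (SE 0.034) of Smad5. Exchanged genotype labels cannot be told apart from a response of the intact copies, since the table holds no allele or Cre counts, and with labels exchanged Smad5 would stand at 0.748 of its control level. The response of the genotype itself was not tested.

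Ventral telencephalon genes were lower in the libraries labelled SmadNes in all 3 pairs, with mean within-pair log2 differences of -1.17 (SF3), -0.44 (SF4) and -0.34 (SF5_6). How far the pattern rests on a single pair of pools stays open, since the highest pair median, -0.297, only restates it. With the block, camera placed the list lower with SF3, SF4 or SF5_6 left out (voom medians -0.353, -0.682 and -1.144, adjusted p 5.95e-12, 2.92e-16 and 2.85e-19), but with an estimated correlation it did not pass even with all pairs (adjusted p 0.598). Cortical neuron genes fell less in each pair, with medians of -0.130, 0.005 and -0.001 against -1.411, -0.480 and -0.297 for the ventral list. The difference between the lists was -0.62 (permutation p 1e-05, the smallest that the resamples can give). That test treats genes as independent, whereas the ventral members moved together, and the list was seen to be low first. Its p therefore cannot decide on a lower share of all neurons. Less ventral tissue in the dissection of SmadNes pools cannot be told apart from an effect of genotype, since both would act within the pairs, where the difference averaged -0.65 (SD 0.453).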
